A study of Homo sapiens with 4 samples.

How the data were processed

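RNA of 4 samples of HT-29, a human colorectal adenocarcinoma cell line, was sequenced. In all 4 the gene for IMP1 (symbol IGF2BP1), an RNA-binding protein of oncofetal tissues, had been targeted with CRISPR/Cas9. Per the labels, 2 libraries came from cells with an empty PiggyBac vector (null) and 2 from cells with a PiggyBac vector carrying FLAG-tagged IMP1 with a short UTR (IMP1-OE), and a liver metastasis grown in a mouse is given as the origin of the lines. The series' design text speaks of 2 cell lines of each genotype. Apart from this, the sources used here do not say whether the replicates were separately derived clones or separate cultures. P-values therefore measure only the spread between these samples, which may be technical.

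Per the labels' protocols, RNA in cleared lysates was broken at random by heat in an alkaline buffer, fragments of 18 to 50 nt were kept, linkers with random-base molecular identifiers were ligated at both ends, ribosomal RNA was depleted from the pooled samples and cDNA was amplified for 15 PCR cycles. Whether the identifiers were used to remove PCR copies is not given in the sources used here, so floors and intervals cover counting error only. Cutadapt 3.5, fastp 0.21, HISAT2 2.1.0, kallisto 0.46.2 and DESeq (with no version) are named in the submitters' processing notes, without roles. The genome build and annotation release are not given in the sources used here, and no coordinates are printed.

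The deposited values are estimated counts, named as kallisto names them per the file headers, for 20322 targets in each library. Each target is a different Ensembl gene represented by 1 transcript, so transcripts of a gene cannot be compared. By the biotypes in the deposited target names, 19621 targets were protein-coding and 311 were marked for nonsense-mediated decay. All estimated counts were whole numbers as deposited and were used without further rounding. Fragments this short can match more than 1 target, and estimated counts can split them, although a split is not visible in whole numbers. The counts of near-identical paralogs and of overlapping targets are therefore uncertain. The counts of the table's top gene, ARSI, carry only 6 significant digits in 3 of the 4 libraries. Symbols came from the deposited target names, and 20299 of the 20322 gene identifiers also matched a table of gene names. The table holds 2 further sample names that match no label used here. They are not analysed here.

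The authors' deposited comparison table gives log2 fold changes with their errors, p-values and adjusted p-values from DESeq, per the submitters' processing notes and the file headers. Its mean normalized count per gene equalled the mean over the 4 libraries after DESeq2 size factors, with a largest relative deviation of 5.32e-10, and positive deposited log2 values mean higher in IMP1-OE. For some genes its log2 fold changes are far smaller in size than DESeq2's unshrunken estimates, and the file does not state a shrinkage.

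Library totals were 10594813 counts (null replicate 1), 9343429 (null replicate 2), 10015212 (IMP1-OE replicate 1) and 10472121 (IMP1-OE replicate 2). A count of 0 allows up to 3 counts per library, which is 0.285 to 0.328 CPM. Before averaging, the 2 libraries of each group were compared by a chi-square test of their counts over genes. The statistic per degree of freedom was 59.1 for null and 20.5 for IMP1-OE, more than counting noise gives, so no 2 libraries were merged as a repeat deposit. This does not show that they are separate cultures.

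Genes were tested with edgeR 4.0.16 (R 4.3.3), with TMM scaling, its default low-count filter (12113 genes kept) and the quasi-likelihood F test with default settings, IMP1-OE against null with no covariate. Adjusted p-values are Benjamini-Hochberg values and 0.05 was the threshold. CPM values are TMM-scaled and given as mean ± SD of the 2 libraries of a group (n = 2 throughout). Log2 fold changes are edgeR's fitted values, IMP1-OE over null, and those of genes with no count in a group are not used as folds. DESeq2 1.42.0, limma 3.58.1 (voom), other scalings and filters, the replicate number as a block, and the omission of each library in turn were the alternatives. The edgeR likelihood ratio test, 2 other variance settings of edgeR, DESeq2 with the block, DESeq2 without each library and the omission of ARSI were added after the data were seen. With 2 libraries against 2, an exact two-sided permutation test cannot give a p under 0.333, so p-values come from models that share information across genes.

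The steps were tested on simulated counts for the same 12113 genes, with the libraries' depths and 200 changed genes in each of 10 simulations of IMP1-OE against null. The changed genes were drawn only from genes above a minimum mean count, so recovery among genes with low counts was not simulated. Each gene's spread was drawn around the trend that edgeR fitted and was equal in both groups. The draws were skewed upward, so their mean lay above the trend. The real null libraries differed more from each other than the IMP1-OE libraries did (SD of log2 differences 0.934 against 0.665). The simulated shares of recovered genes and false calls need not hold for these data. The edgeR test recovered 0.149% of genes changed 2-fold, 0.896% of those changed 4-fold and 11.2% of those changed 8-fold, with 0 to 42 calls per simulation. DESeq2 recovered 14.8%, 71.8% and 92.4% of the same genes. Of its calls, 43.8% were genes simulated without a change, against 4.71% for edgeR and 14.2% for edgeR with the replicate block. The list test called a list of 30 genes shifted by 1 log2 unit in 10 of 10 simulations and 0% of unshifted lists. Simulated genes were independent of each other, while estimated correlations within the real lists reached 0.80. The 0% therefore does not carry over to lists of correlated genes, and smaller shifts were not simulated.

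Fixed before the data were examined were the tests, the alternatives not named above as added, 27 gene lists and the rule for named genes. The lists were the IMP1 family and oncofetal partners, reported IMP1 mRNA partners, let-7 targets, extracellular vesicle biogenesis and cargo, Wnt beta-catenin targets, absorptive enterocyte markers, goblet and secretory markers, epithelial junction and identity, mesenchymal transition, interferon-stimulated genes, NF-kB and inflammatory genes, hypoxia and glycolysis, cholesterol biosynthesis, unfolded protein and integrated stress response, autophagy genes, proliferation genes, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, nuclear OXPHOS subunits, replication-dependent histones, abundant structural noncoding RNAs, long noncoding RNAs of colorectal cancer, immediate early genes, and markers of fibroblasts, endothelium, immune cells and hepatocytes. Lists with at least 5 tested genes (22 lists) were tested with limma's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry, each with Benjamini-Hochberg adjustment over the 22 lists. Camera compares a list with the other genes. With an estimated correlation, its p also comes from the few residual degrees of freedom of these libraries, which leaves it little power. Fry asks whether a list's own genes move on balance to a side, and its mixed test whether they move in either direction.

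IGF2BP1 is named first. Then, per direction, genes past the threshold were to be named by size of change. As fewer than 10 passed in either direction, the 10 genes with the smallest unadjusted edgeR p were named, among genes with a symbol, a mean log2 CPM of at least 2 and both libraries of a group outside the range of the other group. No gene was passed over for a clone-based symbol. From each list described, up to 4 members with the smallest p are named, and some of these are not reported here. Other genes that the text names were chosen after their values were seen.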

Results

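The libraries compared RNA of HT-29 cells whose IMP1 gene had been targeted with CRISPR/Cas9 (labelled null, 2 libraries) with RNA of the same background after IMP1 was put back from a vector (IMP1-OE, 2 libraries). The question the comparison addresses is which mRNAs differ in level when this RNA-binding protein, which the study follows into extracellular vesicles, is present again in colorectal cancer cells. Totals ran from 9343429 to 10594813 counts per library. A large share was assigned to ARSI, the gene of an arylsulfatase. It took 17.8% and 17.3% of the counts of the null libraries and 8.01% and 12.4% of those of the IMP1-OE libraries. With ARSI left out, the top 10 targets together held 6.32% to 7.33% of a library's counts. Whether the fragments assigned to ARSI came from its mRNA was not tested.

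IGF2BP1, the gene of IMP1, was 3.22-fold higher in IMP1-OE, at 8.70 ± 2.75 CPM against 2.68 ± 1.32 CPM in null (mean ± SD of 2 libraries, as for all CPM values here). Its counts were 37 and 16 in the null libraries and 71 and 112 in the IMP1-OE libraries, so the order of the groups follows their labels. The log2 fold change was 1.69 (SE 0.56), with an unadjusted p of 0.0235 and an edgeR adjusted p of 0.453, so the difference did not pass the threshold across all genes. It was 2.30 without null replicate 1 and 1.26 without null replicate 2. Null cells kept IGF2BP1 counts above the floor of 3. Counts do not tell an edited transcript from an intact one, and the deposited target is a transcript of 8796 nt, while the vector carries a short UTR. In the authors' deposited table the log2 fold change of IGF2BP1 is 0.10, with an adjusted p of 0.292.

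Among the genes higher in both IMP1-OE libraries, the smallest p belonged to COL9A3, the gene of a collagen IX chain, at 277 ± 10.4 CPM against 25.8 ± 6.43 CPM in null, a 10.7-fold difference. CLEC3A, a C-type lectin gene of cartilage, was 31.2-fold higher, at 50.9 ± 7.36 CPM against 1.64 ± 0.933 CPM. IGF2, a fetal growth factor whose mRNA gave the IMP family its name, was 7.76-fold higher, at 141 ± 21.3 CPM against 18.2 ± 5.90 CPM. BGN, the gene of the proteoglycan biglycan, was at 559 ± 173 CPM against 36.0 ± 28.6 CPM and PLXND1, a semaphorin receptor gene, at 119 ± 3.60 CPM against 12.6 ± 9.08 CPM. CSPG4, a proteoglycan of the cell surface, was 3.79-fold higher. The adhesion molecule gene MCAM was 3.63-fold higher, the focal adhesion gene LIMS2 3.10-fold, the phosphatase gene PTPN7 5.06-fold and the organic anion transporter gene SLCO4A1 2.34-fold. Of these, 3 moved by over 1.5-fold with a null library left out: the log2 fold change of CLEC3A was 4.96 with all libraries and 5.68 without null replicate 2, that of BGN 3.96, 5.15 without null replicate 1 and 3.31 without null replicate 2, and that of PLXND1 3.24, 4.28 and 2.65 in the same order.

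On the lower side, GNE, which encodes the enzyme that starts sialic acid synthesis, was at 33.9 ± 0.645 CPM in IMP1-OE against 118 ± 3.81 CPM in null, 3.48-fold lower. IQGAP2, a cytoskeletal scaffold gene, was 4.85-fold lower, at 17.7 ± 3.58 CPM against 86.0 ± 6.33 CPM. LGALS3, the gene of galectin-3, was 3.16-fold lower, at 25.4 ± 1.30 CPM against 80.5 ± 11.8 CPM. CKMT1A, a mitochondrial creatine kinase gene, was 15.5-fold lower, but its near-identical copy CKMT1B can take the same fragments, so the size is uncertain. PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, was 2.79-fold lower, the cytochrome P450 gene CYP2S1 3.42-fold, RARRES1 7.27-fold, the membrane skeleton gene EPB41L1 2.51-fold, FXYD3, a regulator of the sodium pump, 4.32-fold, and the amino acid transporter gene SLC6A20 8.39-fold.

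None of these 20 genes passed an edgeR adjusted p of 0.05, and all 20 passed it in the authors' deposited table, where adjusted p was 9.18e-35 for COL9A3, 1.02e-17 for IGF2 and 8.87e-11 for GNE. The edgeR quasi-likelihood test called 0 of 12113 genes, with a smallest adjusted p of 0.0978 (COL9A3). At an unadjusted p under 0.05 it gave 1233 genes, 526 higher and 707 lower in IMP1-OE, where chance alone would give 606. DESeq2 called 164 genes on the same counts, 55 higher and 109 lower, and limma-voom 1. Without null replicate 1 edgeR called 783 genes (337 higher, 446 lower) and DESeq2 1025 (536 higher, 489 lower), and without null replicate 2 edgeR called 48 (18 higher, 30 lower) and DESeq2 263 (135 higher, 128 lower), so the excess of lower DESeq2 calls was absent when either null library was left out. These DESeq2 omissions were chosen after the data were seen. The groups did not overlap for 5230 genes, 43.2% of those tested, where chance gives 33.3%.

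**Figure D1:**
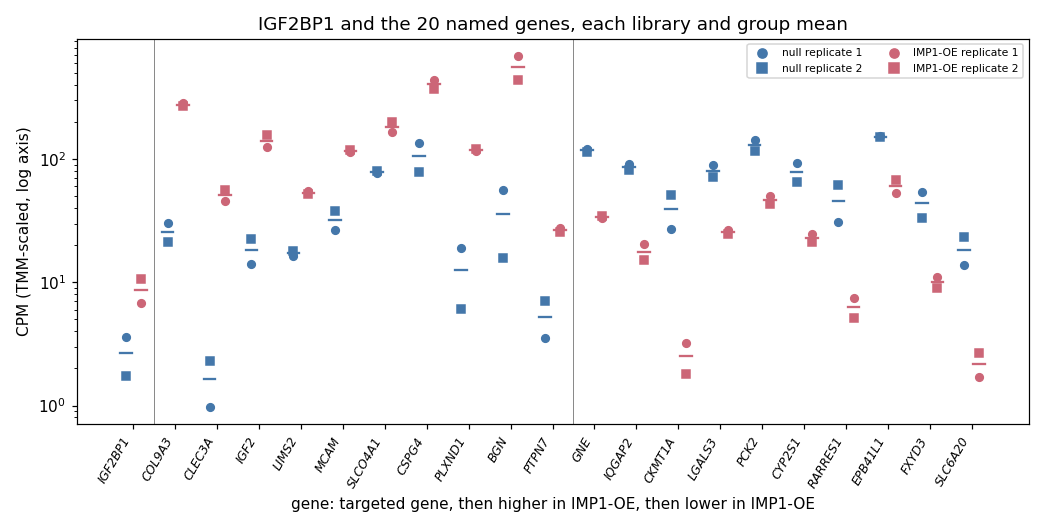
Expression of IGF2BP1 and the 20 named genes in CPM (TMM-scaled, log axis), with a point per library and a line at the mean of each group of 2 libraries. COL9A3 lies at 277 ± 10.4 CPM in IMP1-OE and 25.8 ± 6.43 CPM in null. In every gene shown both libraries of a group lie outside the range of the other group, which was a condition for naming the 20 genes.

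The authors' deposited table calls 164 genes, 55 higher and 109 lower in IMP1-OE, of 12836 with an adjusted p. DESeq2 gave the same 164 genes here, and log10 p-values differed by at most 0.00195. Genes called by both edgeR and the authors numbered 0, since edgeR called 0. Of the authors' calls, 160 were among the genes tested by edgeR, and all 160 had an unadjusted edgeR p under 0.05. The deposited log2 fold changes of 33 of the 164 genes lie within 0.5 of 0, although the unshrunken DESeq2 log2 fold changes of these 33 all exceed 2 in size. SPINK4, a goblet cell peptide gene, is an example: the authors' deposited table gives a log2 fold change of -0.19 with an adjusted p of 4.85e-05, while its level was 0.238 ± 0.0671 CPM in IMP1-OE and 10.0 ± 7.09 CPM in null.

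The IMP1 family and its oncofetal partners rose as a list (median log2 fold change 0.49, camera adjusted p = 0.00614, and adjusted p = 0.436 with an estimated correlation). All 6 tested members were higher in IMP1-OE, with IGF2BP3 at 1.44-fold, HMGA1 at 1.38-fold and HMGA2, a chromatin protein gene, at 2.17-fold, and 0 of the 6 passed adjusted over the list alone. The list includes IGF2BP1 itself, which the vector supplies. Reported IMP1 mRNA partners rose as a list as well (median 0.23, camera adjusted p = 0.0237, and adjusted p = 0.436 with an estimated correlation), with 13 of 16 tested members higher. Adjusted over the list alone, IGF2 (adjusted p = 8.87e-04) was higher and PTGS2, the gene of the prostaglandin enzyme COX-2, was lower (adjusted p = 0.0109), at 0.998 ± 0.874 CPM against 19.5 ± 10.5 CPM, and the remaining members did not pass. MYC stood at 377 ± 13.2 CPM against 270.0 ± 40.7 CPM in null and GLI1 at 3.57 ± 0.602 CPM against 1.06 ± 0.573 CPM. The let-7 targets, which share IGF2BP3, HMGA1, HMGA2 and MYC with those lists, rose with a median of 0.38 (14 of 18 higher, camera adjusted p = 0.0112, and adjusted p = 0.436 with an estimated correlation), and 0 passed adjusted over the list alone. Without null replicate 2 the camera adjusted p was 0.130 for the mRNA partners (median 0.11) and 0.0676 for the let-7 targets, and without IMP1-OE replicate 2 it was 0.106 for the partners. Without members that stand on another list it was 0.207 for the partners and 0.157 for the let-7 targets.

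Genes of extracellular vesicle biogenesis and cargo did not shift as a list. Of 49 tested, 19 were higher and 30 lower in IMP1-OE, with a median log2 fold change of -0.09 (camera adjusted p = 0.422). Without null replicate 1 the direction of the test turned, with an adjusted p of 0.851 and a median of -0.04. HSPA8, a heat shock cognate found in vesicles, was at 4646 ± 512 CPM in IMP1-OE against 2652 ± 371 CPM in null, and VPS28, a subunit of the ESCRT-I sorting complex, at 80.1 ± 2.15 CPM against 158 ± 40.4 CPM. Both passed in the authors' deposited table (adjusted p 0.0137 and 0.0272), and 0 of the 49 passed in edgeR adjusted over the list alone. SDC4, a syndecan gene, was at 151 ± 13.0 CPM against 232 ± 52.3 CPM and PLD2, a phospholipase D gene, at 10.6 ± 2.23 CPM against 24.4 ± 12.8 CPM.

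Genes of cytosolic ribosomal proteins rose together in IMP1-OE, with 76 of 78 higher, a median log2 fold change of 0.47 and a camera adjusted p of 7.94e-17. With an estimated correlation of 0.47 between members, the camera adjusted p was 0.436. RPS7 stood at 1057 ± 69.1 CPM against 505 ± 137 CPM, RPLP2 at 555 ± 75.8 CPM against 280 ± 51.9 CPM, and RPS25 at 600 ± 29.0 CPM against 354 ± 15.5 CPM, and RPS20 was 1.63-fold higher. An unadjusted p under 0.05 was reached by 40 of the 78, all higher, and 0 passed adjusted over the list alone. Of the authors' calls, 6 higher genes were on this list where 0.334 would be drawn by chance (Fisher's exact test, adjusted p = 4.36e-05 over 46 tests, which treats genes as independent). The list stayed past the threshold with the preset correlation when any of the 4 libraries was left out, with medians from 0.37 to 0.63.

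Proliferation genes also rose as a list, with 27 of 32 higher and a median of 0.37 (camera adjusted p = 9.76e-06, and adjusted p = 0.436 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, was at 256 ± 12.2 CPM against 151 ± 15.2 CPM and RRM2, a ribonucleotide reductase subunit, at 464 ± 24.3 CPM against 283 ± 27.1 CPM, and both passed in the authors' deposited table. UBE2C was 1.59-fold and AURKA 1.72-fold higher, and 0 of the 32 passed adjusted over the list alone. Fry's test for movement to a side gave an adjusted p of 0.0944 for this list, and no list passed by it. Fry's mixed test, which does not ask for a shared direction, gave an adjusted p of 0.0256 for this list. It also passed IMP1 mRNA partners, epithelial junction, NF-kB, stress response and immediate early genes (adjusted p 0.0231 to 0.0321). Replication-dependent histone genes rose with a median of 0.36 (13 of 16 higher, camera adjusted p = 0.00640, and adjusted p = 0.465 with an estimated correlation), with H2BC4 at 1.69-fold, H3C4 at 1.54-fold and H4C3 at 1.61-fold, and histone genes are near-identical, so single members are uncertain. Hypoxia and glycolysis genes rose with a median of 0.28 (20 of 27 higher, camera adjusted p = 0.0146, and adjusted p = 0.436 with an estimated correlation). Its members with the smallest p lay on both sides, with ENO2 and GAPDH 2.00-fold and 1.69-fold higher and VEGFA and BNIP3L 2.16-fold and 2.27-fold lower. Adjusted over the list alone, 0 histone and 0 hypoxia and glycolysis genes passed. Without null replicate 2 the camera adjusted p of the histones was 0.0676 (median 0.20), and without IMP1-OE replicate 1 that of hypoxia and glycolysis was 0.150.

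Mitochondrially encoded mRNAs fell as a list in IMP1-OE, with 12 of 13 lower and a median log2 fold change of -0.70 (camera adjusted p = 1.26e-04, 0.436 as the adjusted p with an estimated correlation). Adjusted over the list alone, MT-CO1 (2.03-fold lower), MT-CO2 (1.90-fold), MT-ND6 (2.17-fold) and MT-ATP6 (2.15-fold) passed. MT-CO1 was at 674 ± 105 CPM against 1366 ± 119 CPM, and MT-CO1 and MT-CO2 passed in the authors' deposited table. The list stayed past the threshold with the preset correlation without any of the 4 libraries, with medians from -1.02 to -0.49. Nuclear genes of the same respiratory complexes did not shift (25 of 35 lower, median -0.08, camera adjusted p = 0.250), with UQCRFS1 at 1.41-fold, COX6C at 1.39-fold and NDUFV1 at 1.29-fold lower. Without null replicate 2 the nuclear list passed as lower (adjusted p = 0.00159, median -0.25), and without null replicate 1 its median was 0.04.

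Genes of the unfolded protein and integrated stress response fell as a list, with 21 of 32 lower and a median of -0.28 (camera adjusted p = 0.0146, 0.465 as the adjusted p with an estimated correlation). CHAC1, a glutathione-degrading enzyme gene, was at 3.38 ± 0.737 CPM against 15.1 ± 1.21 CPM and passed adjusted over the list alone (adjusted p = 0.0406). The amino acid synthesis genes ASNS and PSAT1 were 2.20-fold and 2.02-fold lower, and HERPUD1, a gene of protein degradation at the endoplasmic reticulum, 1.78-fold lower. At an unadjusted edgeR p under 0.05, 8 members were lower and 2 higher, the latter being SDF2L1 (1.63-fold) and PDIA4 (1.38-fold). CHAC1, ASNS and PSAT1 passed in the authors' deposited table. The camera adjusted p was 0.345 without null replicate 1 and 0.102 without IMP1-OE replicate 2. Autophagy genes (21 of 31 lower, median -0.15, camera adjusted p = 0.0706) and cholesterol biosynthesis genes (18 of 25 higher, median 0.12, adjusted p = 0.0831) did not pass. The autophagy receptor genes CALCOCO2, SQSTM1 and OPTN were 1.97-fold, 1.71-fold and 2.58-fold lower, of which SQSTM1 passed in the authors' deposited table. INSIG1 and STARD4, genes of sterol regulation and transport, were 1.39-fold and 1.54-fold higher. Without null replicate 2 both lists passed (adjusted p 0.0276 and 0.0208), and without IMP1-OE replicate 1 the autophagy list did (0.0277).

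Interferon-stimulated genes fell in IMP1-OE as a list, with all 37 tested members lower, a median log2 fold change of -1.85 and a camera adjusted p of 3.11e-09. With an estimated correlation of 0.80 between members the adjusted p was 0.465, and without null replicate 2 the median was -0.27 (camera adjusted p = 0.0161). ISG20, an exonuclease gene, was at 11.4 ± 1.60 CPM against 40.2 ± 13.2 CPM and passed adjusted over the list alone (adjusted p = 0.0418). IFIT2 was at 4.95 ± 2.29 CPM against 26.0 ± 15.9 CPM and OASL at 17.2 ± 4.22 CPM against 53.2 ± 26.0 CPM, and ISG20, IFIT2 and OASL passed in the authors' deposited table. Much of the difference came from null replicate 2, in which 36 of the 37 genes were higher than in null replicate 1, by a median of 2.42 log2 units. The exception was ISG20, at 49.6 CPM in null replicate 1 and 30.9 CPM in null replicate 2, so its lower level in IMP1-OE did not come from null replicate 2. IFI44 was at 264 CPM in that library, 31.5 CPM in null replicate 1 and 17.5 ± 4.42 CPM in IMP1-OE. Without null replicate 1 the median log2 fold change was -2.56.

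NF-kB and inflammatory genes fell as a list (10 of 13 lower, median -0.55, camera adjusted p = 0.0146, and adjusted p = 0.465 with an estimated correlation), with NFKB2 at 1.95-fold and the cytokine gene IL32 at 3.64-fold lower. IL18, another cytokine gene, was at 1.19 ± 0.739 CPM against 4.21 ± 0.542 CPM, and ICAM1, an adhesion molecule gene, at 6.52 ± 0.0620 CPM against 9.10 CPM in null replicate 1 and 21.4 CPM in null replicate 2. The listed genes stood higher in null replicate 2 than in null replicate 1 for 9 of 13 genes, and without null replicate 2 the median was -0.23 (camera adjusted p = 0.546). Mesenchymal transition genes fell as well (9 of 10 lower, median -0.96, camera adjusted p = 0.0264, and adjusted p = 0.436 with an estimated correlation). TGFB1 was at 2.85 ± 0.536 CPM against 5.28 CPM in null replicate 1 and 55.3 CPM in null replicate 2, while MMP14, a membrane-bound protease gene, was at 7.94 ± 0.477 CPM against 16.7 ± 3.37 CPM. Without null replicate 2 the median of this list was -0.37 (camera adjusted p = 0.0676), and the camera adjusted p was 0.0595 without IMP1-OE replicate 1 and 0.0678 without IMP1-OE replicate 2. Adjusted over the list alone, 0 NF-kB genes and 0 mesenchymal genes passed. Of the immune cell markers only 5 were testable, 4 of them lower (median -0.84, camera adjusted p = 0.404). CD74 and CD14 were at 61.9 and 52.3 CPM in null replicate 2 and at 7.82 and 18.8 CPM in null replicate 1.

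Epithelial junction and identity genes fell as a list, with 23 of 29 lower and a median of -0.22 (camera adjusted p = 0.0264, 0.436 as the adjusted p with an estimated correlation). The tight junction genes CLDN1, OCLN and CLDN7 were 2.05-fold, 1.56-fold and 1.56-fold lower. The camera adjusted p was 0.142 without null replicate 1 and 0.196 without IMP1-OE replicate 2, and 0 of the 29 passed adjusted over the list alone. Wnt beta-catenin targets did not pass (15 of 20 higher, median 0.27, camera adjusted p = 0.0793), with SP5, a transcription factor gene, at 2.37-fold higher and CCND1, the gene of cyclin D1, at 1.34-fold lower. Immediate early genes did not pass either (16 of 22 lower, median -0.44, adjusted p = 0.158), with DUSP6 at 1.61-fold higher and JUNB at 1.49-fold lower.

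Goblet and secretory markers (15 of 17 lower, median -0.95, camera adjusted p = 0.0831) and absorptive enterocyte markers (8 of 12 lower, median -0.08, adjusted p = 0.859) did not pass with all libraries, and with an estimated correlation their adjusted p-values were 0.626 and 0.949. Their direction turned with the null library used. With the preset correlation and without null replicate 2 both lists were lower in IMP1-OE (medians -1.64 and -0.59, adjusted p 6.12e-09 and 3.31e-04), and without null replicate 1 the medians were 0.40 and 1.01 (adjusted p 0.126 and 0.00536). With library totals as the scale and the preset correlation, the adjusted p of the goblet list was 0.0404, and without IMP1-OE replicate 1 it was 0.0479 (median -0.95). SPINK4 passed adjusted over the goblet list alone (adjusted p = 0.0128), while SPDEF, a transcription factor gene of secretory cells, was 1.97-fold higher (log2 fold change 0.98, SE 0.28). CDHR5, a brush border cadherin gene, was at 10.7 ± 2.77 CPM against 23.6 ± 2.24 CPM.

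**Figure D2:**
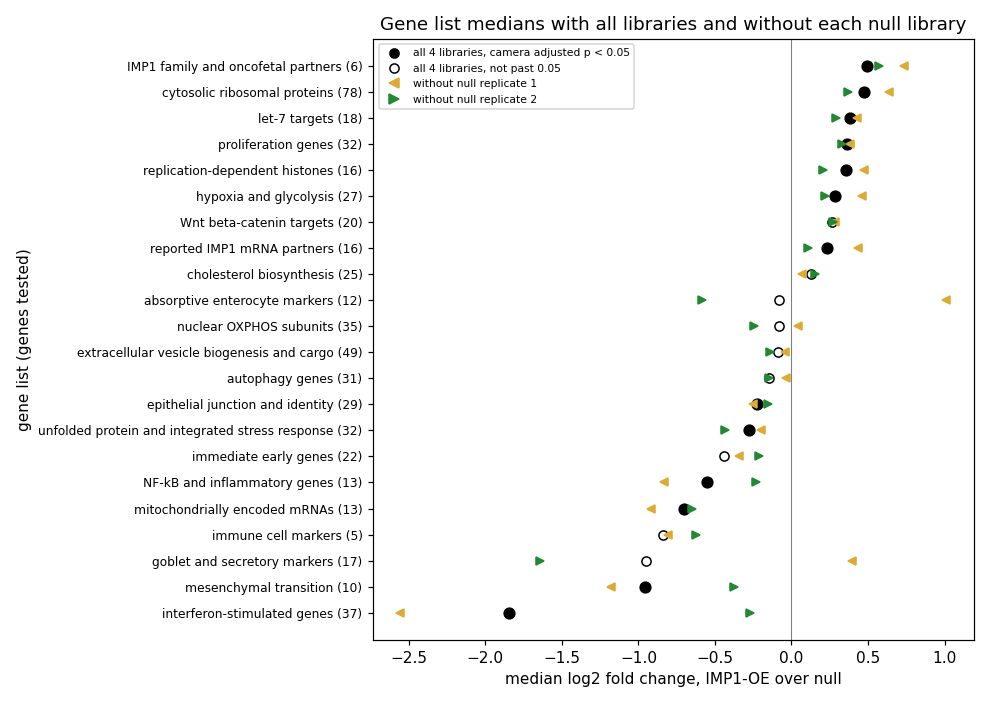
Median log2 fold change (IMP1-OE over null) of each tested gene list, with the number of genes in brackets, for all 4 libraries (circles, filled where the camera adjusted p with the preset correlation was under 0.05) and without null replicate 1 or 2 (triangles). Ribosomal proteins keep a median between 0.37 and 0.63, while interferon-stimulated genes move from -1.85 to -0.27 without null replicate 2.

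**Figure D3:**
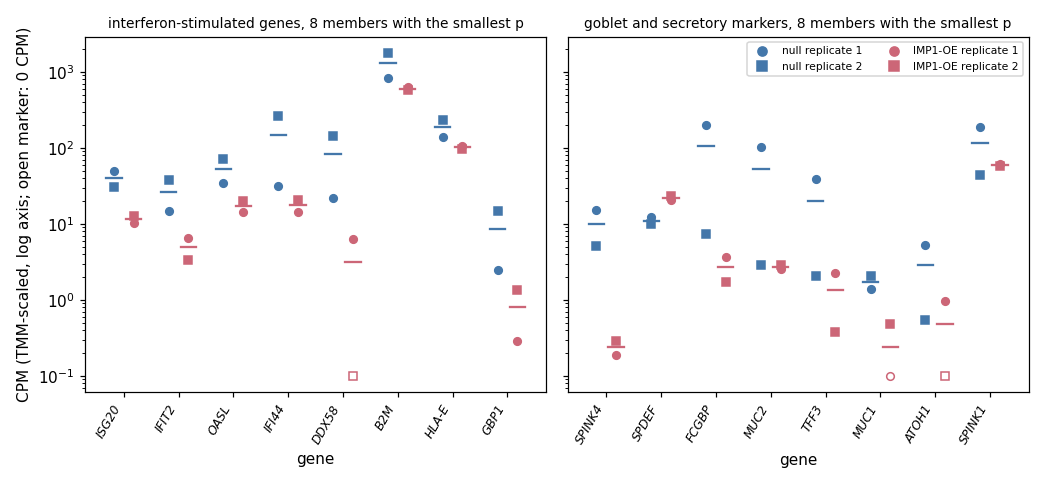
CPM (TMM-scaled, log axis) of 8 interferon-stimulated genes and 8 goblet and secretory markers, those with the smallest p in each list, with a point per library, an open marker for 0 CPM and a line at the mean of each group of 2 libraries. IFI44 lies at 264 CPM in null replicate 2 and 31.5 CPM in null replicate 1, while SPINK4 lies at 0.238 ± 0.0671 CPM in IMP1-OE and 10.0 ± 7.09 CPM in null.

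Markers of other cell types were mostly under the filter. Of 14 fibroblast, 10 endothelial and 15 hepatocyte markers, 2, 3 and 2 were testable, too few for a list test. SERPINA1, a hepatocyte marker that intestinal epithelium also expresses, was at 705 ± 27.6 CPM against 331 ± 149 CPM and passed adjusted over the 2 testable hepatocyte markers (adjusted p = 0.0289), while TF, a transferrin gene, was at 5.18 ± 2.48 CPM against 2.90 ± 0.230 CPM. ACTA2 and COL1A1 of fibroblasts were at 1.85 ± 0.335 and 1.38 ± 1.01 CPM against 7.84 ± 7.63 and 2.37 ± 1.49 CPM. ESAM and PECAM1 of endothelium differed 1.30-fold and 1.14-fold. Of 25 long noncoding RNAs, 1 (TUG1, 16.5 ± 3.35 CPM against 17.7 ± 1.22 CPM) was a target of the table, and of 21 abundant structural noncoding RNAs 0 were. Apart from TUG1, these groups were not measured here.

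The 4 libraries did not separate mainly by group. The first principal component of log2 CPM, with 50.1% of the variance, set null replicate 2 (score 69.5) apart from null replicate 1 (-8.88) and the IMP1-OE libraries (-34.6 and -26.1). Across genes, Pearson's r of log2 CPM was 0.916 between the null libraries and 0.959 between the IMP1-OE libraries, where genes are not independent replicates. Between groups, r with IMP1-OE replicates 1 and 2 was 0.945 and 0.936 for null replicate 1, and 0.909 and 0.913 for null replicate 2. Null replicate 1 was thus closer to both IMP1-OE libraries than to null replicate 2. A difference of over 2 log2 units was found for 591 genes between the null libraries and for 270 between the IMP1-OE libraries. Between null replicate 1 and IMP1-OE replicates 1 and 2 it was found for 387 and 430 genes.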

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

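Tests marked as added were chosen after the data were seen. The count of genes past the edgeR threshold was 0 with size factors of DESeq2, library totals, the stricter filter, a fold limit or protein-coding targets only, and also with ARSI left out (added). Without a filter it was 22. Limma-voom gave 1 and DESeq2 164, and, added, the edgeR likelihood ratio test 155, edgeR with bias-adjusted deviances 1 and with a robust prior 1. The cause was not tested. In the simulations, which gave both groups an equal spread, DESeq2 made more calls and more false ones. Leaving out a library gave 0 to 783 calls in edgeR and, added, 27 to 1025 in DESeq2 (27 and 33 without IMP1-OE replicate 1 or 2). The ends 783 and 1025 lack null replicate 1, which leaves null replicate 2 as the null group, a lone library assumed to vary like the IMP1-OE libraries. Without null replicate 2 the counts were 48 and 263, and without either IMP1-OE library edgeR gave 0. With the replicate block, edgeR gave 15 calls and DESeq2 91 (added), and the block took the count of lists from 13 to 15, with Wnt beta-catenin targets (adjusted p = 0.0462) and goblet markers (0.0254) now past the threshold. The labels do not say that replicate numbers mark a shared batch, and with 2 pairs the correlation of deviations between same-numbered libraries was 0.123, which neither shows nor excludes a shared batch, so the numbers were not used as pairs. The 13 lists past the threshold became 0 with an estimated correlation and 14 with library totals. Without members that stand on another list they became 10 (camera adjusted p 0.207 for IMP1 mRNA partners and 0.157 for let-7 targets, while the IMP1 family had too few members left to test). The epithelial junction, hypoxia and glycolysis, and mesenchymal lists among the 13 had estimated correlations of 0.00077, -0.0085 and -0.017. These lie below the preset 0.01, so correlation between members does not account for the loss of these lists. The form with an estimated correlation also takes its p from the few residual degrees of freedom of these libraries. The epithelial junction list, for example, went from an unadjusted camera p of 0.0156 to 0.114. That form could hardly pass any list here, so its adjusted p-values show neither a shift nor its absence. The log2 fold change of IGF2BP1 ranged from 1.26 to 2.32 and its adjusted p from 0.0830 to 1. For the 20 named genes, no alternative reversed a direction, 224 values kept their side of the threshold and 176 passed it. Genes shared with the authors' deposited table were 0 at an adjusted p of 0.01 too, which follows from the 0 edgeR calls and is no further check. Library totals moved the median of all genes by 0.08 log2 units. Tests of transcripts were not run, as the table holds 1 transcript per gene. At this depth and with 2 libraries per group, edgeR recovered 11.2% of 8-fold changes, simulated only in genes above a minimum mean count. Thus 0 calls does not show that genes were unchanged.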

Other observations

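Among the tests here, those on IGF2BP1 counts in null replicate 2, on this set of leukocyte genes and on other groupings of the libraries were chosen after the values had been seen.

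The null libraries differed from each other in differentiation genes. MUC2, the main intestinal mucin gene, was at 102 CPM in null replicate 1, 2.85 CPM in null replicate 2 and 2.71 ± 0.200 CPM in IMP1-OE. FCGBP, another mucus protein gene, was at 201, 7.33 and 2.66 ± 1.35 CPM in the same order, TFF3, a trefoil peptide gene, at 38.2, 2.08 and 1.33 ± 1.35 CPM, and CEACAM6, an adhesion molecule gene, at 137, 1.20 and 6.23 ± 1.69 CPM. The 17 goblet and secretory markers were lower in null replicate 2 than in null replicate 1 by a median of -2.64 log2 units, and 2 of the 17 were higher. Of 10000 random lists of 17 genes matched on mean expression, 95% had medians between -0.33 and 0.41. This describes 2 libraries and has no replicate check.

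The interferon-stimulated genes were higher in null replicate 2 than in null replicate 1 by a median of 2.42 log2 units, against -0.21 to 0.18 for 95% of 10000 matched lists of 37 genes, so the lower depth of that library, which would touch matched genes alike, is argued against. Human immune cells or their RNA are argued against too. The 7 leukocyte genes PTPRC, CD3D, CD3E, CD2, MS4A1, TYROBP and FCER1G together had 0 counts in null replicate 2, 0 in null replicate 1 and IMP1-OE replicate 1, and 9 in IMP1-OE replicate 2. However, CD74 and CD14 of the fixed immune marker list were higher in null replicate 2 (61.9 and 52.3 CPM, against 7.82 and 18.8 CPM in null replicate 1). Counts on human targets cannot test for mouse cells, and the lines came from a metastasis grown in a mouse. A swap with an IMP1-OE library would bring a high IGF2BP1 count, and null replicate 2 had 16 counts, the lowest of the 4. What stays open, beside mouse cells, is a difference in culture state or between derived lines, which the labels do not describe and which was not tested. Since IMP1-OE and null replicate 1 differ by a median of -0.27 in these genes, a hypothesis that IMP1 lowers them may rest largely on that library.

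The rise of ribosomal protein genes was weighed against properties of the libraries. For each of the 78 genes, 3 genes outside the list were matched on transcript length and expression. These 234 genes had a median log2 fold change of 0.092 (bootstrap 95% interval 0.045 to 0.13), 19.4% of the list's 0.47. By this estimate, transcript length would account for a small part of the rise. The estimate met the limit set beforehand for arguing against transcript length, while the upper end of the interval exceeded it. With ARSI left out and library totals as the scale, the list's median was 0.43, so neither the lower share of ARSI counts nor the scaling produced it. IMP1 re-expression is consistent with the rise and is the difference the design names, but a difference in growth rate between the lines stays open as well, since proliferation genes rose too and growth was not measured here. With 2 libraries per group, the link to IMP1 remains a hypothesis. The camera adjusted p of 0.436 under an estimated correlation does not decide it, since no list passed in that form.

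Targets at 0 in both libraries of a group and at 20 or more counts in both of the other were HERC3 (0 and 0 counts in null, 121 and 70 in IMP1-OE), TRPM2 (0 and 0, 79 and 81), PWP2 (71 and 122, 0 and 0), TMEM265 (29 and 103, 0 and 0) and the symbol-less ENSG00000285547 (169 and 135, 0 and 0) and ENSG00000288699 (61 and 85, 0 and 0). They and the minimum of 20 counts were chosen after the values were seen. The other 2 groupings of the 4 libraries into pairs gave 4 such targets each, against 6 for null and IMP1-OE. Such on and off patterns may come from the division of short fragments between overlapping or near-identical targets. Among 84 targets at 0 in some library and at 50 or more counts in another, 32.1% were read-through or symbol-less targets, against 2.43% of 10528 others (odds ratio 18.99, 95% interval 11.3 to 31.1, Fisher's exact test). Whether HERC3, TRPM2, PWP2 and TMEM265, which have symbols and are no read-through targets, follow the same cause was not tested.

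DESeq2 called 164 genes between null and IMP1-OE, and the highest count among the other 2 groupings of the libraries into pairs was 8. The real grouping was the only 1 of the 3 with as many calls, and 3 groupings are too few for a share under 0.05. Each of the other 2 pairs a null with an IMP1-OE library. A real group difference would widen the spread within such pairs and lower their calls, so they are no neutral measure of chance.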
